A study of Mus musculus with 23 samples.

How the data were processed

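The tibialis anterior muscle of wild-type and RE-RE mice was measured at ZT0 and ZT12, with or without 6-OHDA injections, in 23 libraries of total RNA read as pairs. Per the submitters' processing notes the tools were FastQC 0.11.8, Trim Galore 0.5.0, HISAT2 2.1.0, featureCounts 1.6.2 and edgeR 3.30.0, with the GRCm38 genome. The deposited table holds log2 FPKM for 14500 genes, log2(FPKM + 0.01), from -6.64, the value of an FPKM of 0, to 16.6. Whether the authors applied a factor between libraries is not stated. The notes give no read counts.

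Gene symbols, coordinates and exon lengths came from GENCODE M21, which gave a length for 14435 genes. Genes with an FPKM of at least 1 in at least 2 libraries were tested, 12855 in all. The log2 values were fitted as deposited with limma 3.58.1 in R 4.3.3, with 1 mean per group, lmFit, contrasts.fit and eBayes with a trend, and residual spread pooled over the 8 groups. The median residual SD was 0.451 in RE-RE and 0.216 in wild-type groups (0.305 pooled), larger in RE-RE for 91.6% of genes, so pooled errors and p values are too small for RE-RE comparisons and too large for those within wild-type mice. The contrasts were ZT12 minus ZT0 in each genotype and treatment, 6-OHDA minus sham in each genotype as the mean of both times, RE-RE minus wild-type in sham muscle, and the differences between these effects. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. FPKM means and SD were taken on the linear scale. Of 33 gene lists written down beforehand, the 29 with at least 3 tested genes were tested by camera with its preset correlation of 0.01 and again with an estimated correlation. The gene lists, contrasts, named-gene rule and most alternatives were chosen before the data were examined. The named genes are the clock genes in comparisons of time and Arntl in all, the 5 largest rises and 5 largest falls with a mean log2 FPKM of at least 1 in a compared group and a named gene symbol, and up to 4 genes with the smallest p of each list called or with at least 3 members past the test. Where fewer than 5 genes passed, the 5 with the smallest p were named. Tables and plots used python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Clock scores were compared by exact two-sided permutation, of the times for a time effect and of treatment or genotype within each time for a difference between effects. The latter exchange also removes a difference between groups that both times share, so its p does not test a change of the time effect alone.

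Depth was estimated from the steps between the smallest FPKM values of each library and the exon lengths, since a gene with few reads takes values at whole multiples of 1 read. In each library 86.4% to 94.7% of the values up to 20 reads were whole within a tolerance of 0.1 read. On simulated data, where most genes had an exact length, the per-million total behind the FPKM unit was recovered within 0.0033%. The sum of recovered reads over genes was not checked in this way. At the floor stood 261 to 520 genes per library. Recovered reads over the reads implied by the FPKM unit ranged from 0.839 to 1.52, with a median of 1.15. This ratio differed with treatment. Its means at ZT0 and ZT12 were 1.25 and 1.22 in wild-type sham and 0.939 and 1.02 in wild-type 6-OHDA muscle. They were 1.405 and 1.384 in RE-RE sham and 1.17 and 0.989 in RE-RE 6-OHDA muscle. Scaling by own totals of recovered reads, an alternative below, removes these differences. The fits were tested on simulated data with the same groups, 200 changed genes per run and 5 runs. A change of 1 log2 unit was called for 54.3% of genes in the wild-type sham time comparison, 34.6% in RE-RE sham muscle, 79.4% for 6-OHDA in wild-type mice, 59.7% for 6-OHDA in RE-RE mice and 20.6% for the change of the time effect in wild-type mice. False calls made up 4.86% to 7.02% of calls. The simulated noise of a gene had the same spread in all groups. These rates therefore leave out the larger spread of RE-RE muscle and do not carry over to RE-RE comparisons.

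Alternatives were log2(FPKM + 1), no filter, a mean log2 FPKM of at least 1, quantile normalization, array weights, age as a covariate, the replicate numbers as a block (4239 genes for 6-OHDA in wild-type mice), only the samples of the compared groups, and leaving out each library. Added after seeing the data were limma-voom on recovered reads, own totals of recovered reads, a GC adjustment, removal of libraries that stood apart, and a covariate for regeneration. Sequencing batches are not given in the labels. Raw reads, splicing and isoforms were not analysed here, and lists with fewer than 3 tested genes were left out. The value of a named gene that is withheld is not reported here.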

Results

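Gene expression was measured by paired-end sequencing of total RNA from the tibialis anterior, a fast muscle of the lower leg, in female C57BL/6 mice. The 23 libraries form 8 groups set by genotype, treatment and time of day. The RE-RE mice carry a stopped form of Bmal1, the clock gene also called Arntl, that is switched back on by Syt10-Cre and Hsa-Cre. Hsa-Cre acts in skeletal muscle and Syt10-Cre in neurons that include those of the suprachiasmatic nucleus. Treated muscles had repeated injections of 50 mg/kg 6-OHDA, a toxin taken up by sympathetic nerve endings, and sham muscles were not injected. Zeitgeber time (ZT) 0 is lights on and ZT12 is lights off. Wild-type sham muscle has 4 libraries at ZT0 and 3 at ZT12, and wild-type 6-OHDA muscle has 4 at each time, at 12 to 18 weeks of age for sham and 12 to 16 weeks for 6-OHDA. RE-RE muscle has 2 libraries at each time under each treatment, taken at 10 to 11 weeks of age for sham and 12 to 18 weeks for 6-OHDA. The deposited table gives log2 FPKM without read counts. Reads recovered from its smallest values came to 21.1 to 36.1 M per library, with a median of 28.1 M. Transcripts of the mitochondrial genome took 18.6% ± 2.27 (SD, n = 4) of the recovered reads in wild-type sham muscle at ZT0, and 9.57% ± 2.57 (SD, n = 4) in 6-OHDA muscle, and at ZT12 17.9% ± 2.56 (SD, n = 3) and 13.2% ± 2.32 (SD, n = 4).

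Comparing ZT12 with ZT0 in uninjected wild-type muscle asks which genes of the muscle clock differ between the times. Arntl (ENSMUSG00000055116, GRCm38 chromosome 7, 113207465 to 113314126), an activator at the centre of the clock, fell from 14.2 ± 1.74 FPKM at ZT0 (SD, n = 4) to 2.03 ± 0.16 at ZT12 (SD, n = 3). That is 6.94-fold lower (log2 -2.79 ± 0.18 SE, limma adjusted p = 7.41e-08), and lower in 3 of 3 ZT12 libraries than in any ZT0 library. Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), a transcription factor driven by the clock, rose 11.4-fold, from 3.27 ± 0.931 to 36.6 ± 6.98 FPKM (adjusted p = 1.74e-05). Per2 (ENSMUSG00000055866, chromosome 1, 91415982 to 91459324), which represses the clock's activators, rose 9.21-fold, from 0.611 ± 0.103 to 5.67 ± 0.578 FPKM (adjusted p = 4.25e-05). Npas2, which can take the place of Clock as Arntl's partner, fell 10.6-fold, from 1.05 ± 0.277 to 0.0887 ± 0.0209 FPKM.

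Of 6 genes in a list named for the clock's positive limb, and called so below, 4 fell (5 adjusted over the list alone): Arntl, Npas2, Clock and Nfil3. The name does not describe all members, since Nfil3 and Cry1 are repressors. Cry1 had a log2 difference of -0.41 that did not pass. Of 12 clock targets with E-boxes or D-boxes in their promoters, 8 rose (10 adjusted over the list alone), among them Per1 (log2 2.22 ± 0.47 SE), Per3 (2.24 ± 0.40), Ciart (1.89 ± 0.28) and Tef (1.04 ± 0.20). Nr1d1, in the same clock lists, had a difference of -0.32 that did not pass. Of 19 clock output genes of muscle, 3 rose (8 up and 1 down adjusted over the list alone): Usp2, a deubiquitinase, Dgat2, which makes triglyceride, and Tspan4, a tetraspanin. Of 17 immediate early genes that answer to cyclic AMP and CREB, 1 fell, Ier2 (6 adjusted over the list alone), and the list's median was -0.74. All 4 lists were called by camera, and all 4 calls held with an estimated correlation, at adjusted p of 3.9e-06, 0.00981, 0.00981 and 0.0133. The other 6 lists called with the preset correlation lost that call, and in them 1 of 14 glucocorticoid-induced genes rose, and 1 of 14 lipid-synthesis genes rose and 1 fell (2 up, and 1 up and 3 down, adjusted over the list alone). The median was -0.44 for macrophage genes, -0.21 for endothelial genes, 0.33 for fatty acid use and -0.33 for lipid synthesis (adjusted p = 0.874, 0.664, 0.239 and 0.275 with an estimated correlation). It was 0.36 for glucocorticoid-induced genes and 0.30 for targets of Nrf2 (adjusted p = 0.221 and 0.0963 with an estimated correlation).

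Among the largest differences, Arrdc2, an arrestin-domain gene, rose 6.65-fold, from 10.2 ± 7.70 to 58.3 ± 16.7 FPKM, and Slc10a6, a carrier, 4.95-fold. Ppp1r3c, which targets a phosphatase to glycogen, fell 5.01-fold, from 166 ± 49.7 to 32.0 ± 4.52 FPKM. Pnpla3, a lipid-droplet enzyme, fell (log2 -1.91 ± 0.33 SE), as did Pim1, a kinase (-2.08 ± 0.47), and Apold1, a gene of endothelial cells (-1.89 ± 0.35). In all, 83 of 12855 genes passed at an adjusted p under 0.05 in limma, 34 higher and 49 lower at ZT12. Scaled by each library's own total of recovered reads, 38 were higher and 30 lower. The count was 55 without ZT0 library 3, 39 without ZT12 library 5, 37 without library 6 and 25 without library 7. Without library 7, Per1, Per3, Clock, Usp2, Dgat2, Slc10a6, Ier2, Arrdc2, Pnpla3 and Pim1 no longer passed (log2 2.05, 2.18, -0.98, 1.32, 1.57, 2.23, -0.95, 2.56, -1.85 and -2.12), whereas Arntl, Npas2, Dbp, Per2, Ciart and Ppp1r3c passed without any 1 library.

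The same comparison in 6-OHDA muscle, and the test of the difference between both, ask whether the time difference is altered in injected muscle. Loss of sympathetic nerve endings is not measured in these data. Arntl fell 6.69-fold in injected wild-type muscle, from 9.84 ± 0.734 FPKM at ZT0 to 1.48 ± 0.263 at ZT12 (SD, n = 4 each; log2 -2.74 ± 0.17 SE, limma adjusted p = 2.72e-08). Dbp rose 9.80-fold, from 3.63 ± 0.416 to 36.4 ± 9.26 FPKM (adjusted p = 1.38e-05). Per2 rose 6.40-fold, from 0.954 ± 0.315 to 5.99 ± 0.887 FPKM (adjusted p = 0.000122). Each of these was higher or lower in 4 of 4 ZT12 libraries than in any ZT0 library. Per1 rose 9.01-fold and Hlf, a relative of Dbp, 5.23-fold.

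Of the positive limb, 3 of 6 genes fell (4 adjusted over the list alone), and 8 of 12 E-box and D-box targets rose (10 adjusted over the list alone). Of 19 clock output genes, 5 rose (11 adjusted over the list alone), with Usp2 at a log2 difference of 1.49, Dgat2 at 1.43 and Tcap, a protein of the sarcomere's Z-disc, at 1.40 ± 0.28 SE. Of 14 glucocorticoid-induced genes, 4 rose (8 adjusted over the list alone), Arrdc2, Tsc22d3 (1.08), Klf9 (0.66) and Pik3r1 (0.57). These 4 lists held their camera call with an estimated correlation, at adjusted p of 0.00013, 0.00292, 0.00292 and 0.00292. The immediate early genes were not called (median -0.14). Of 18 fatty acid use genes, 2 rose, Plin5 and Mlycd (4 adjusted over the list alone; median 0.41, adjusted p = 0.189 with an estimated correlation). The other 8 lists called with the preset correlation had no member past the test. Medians were -0.71 for regeneration, -0.53 for erythroid and 0.68 for mitochondrial-genome genes (adjusted p = 0.408 with an estimated correlation), -0.52 for denervation genes (0.466), -0.70 for macrophage genes, 0.30 for oxidative phosphorylation and 0.23 for glycolysis (0.484), and -0.70 for extracellular matrix (0.493). The glycolysis call ended under quantile normalization, at a median of 0.08.

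Arrdc2 rose 16.2-fold, from 2.17 ± 0.386 to 35.7 ± 9.38 FPKM, and Inmt, a methyltransferase, 10.9-fold. Spon2, a secreted matrix protein, fell 13.2-fold, from 5.82 ± 2.69 to 0.469 ± 0.338 FPKM, and Adamts4, a matrix protease, fell 6.55-fold. In all, 86 of 12855 genes passed in limma, 71 higher and 15 lower at ZT12. Leaving out ZT0 library 1 or 3 gave 44 or 41, and leaving out ZT12 library 5, 7 or 8 gave 34, 51 or 42. Without ZT0 library 1, Tcap, Tsc22d3, Klf9, Mlycd and Inmt no longer passed (log2 1.24, 0.93, 0.62, 0.67 and 2.89), nor did Hlf without ZT12 library 5 (2.31). Own totals shifted the median of all genes to -0.12.

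The difference between the 2 time effects was tested directly. The time difference in Arntl changed by 0.05 log2 units with 6-OHDA (95% confidence interval -0.47 to 0.57), in Dbp by -0.21 ± 0.45 SE and in Per2 by -0.52 (interval -1.46 to 0.41). Of 12855 genes, 1 passed in limma, Gm23823, a small nucleolar RNA of 124 nucleotides listed at 0 in some groups, and 278 had an unadjusted p under 0.05. Without wild-type sham ZT12 library 5 or 6-OHDA ZT0 library 4, 2 passed. Among the smallest p that did not pass are Apold1 (2.52 ± 0.47, adjusted p = 0.254) and Klf2 (2.07 ± 0.45, adjusted p = 0.846), both genes of endothelial cells. Camera called 11 lists with the preset correlation and 0 with an estimated one. Immediate early genes had a median of 0.62 (0 of 17 members passed, 3 adjusted over the list alone), glucocorticoid-induced genes of 0.51 and the positive limb of 0.21 (adjusted p = 0.143 with an estimated correlation for each). Denervation genes had a median of -0.66 and mitochondrial-genome genes of 0.79 (adjusted p = 0.456 with an estimated correlation for both). Own totals shifted the median of all genes to -0.14. Of the genes past the test in the sham comparison, 34 also passed in the same direction in 6-OHDA muscle, 22 higher and 12 lower, where independence would give 0.188 and 0.0572. That count was 14 without wild-type sham ZT12 library 7, 17 without library 5 and 21 without library 6, and 22, 19 and 21 without 6-OHDA ZT0 library 3 and ZT12 libraries 5 and 8.

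A clock score per library, defined after the data were seen, gives these time effects as single numbers: the summed log2 FPKM of the E-box and D-box targets minus that of the positive limb, divided by their 18 genes. It was higher at ZT12 by 1.5 ± 0.166 (SE) in wild-type sham muscle and by 1.55 ± 0.153 in 6-OHDA muscle (exact two-sided permutation p = 0.0286 for each). The change with 6-OHDA was 0.0529, with a 95% confidence interval of -0.428 to 0.534 (exact two-sided permutation p = 0.647, adjusted over 4 comparisons 0.647).

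**Figure D1:**
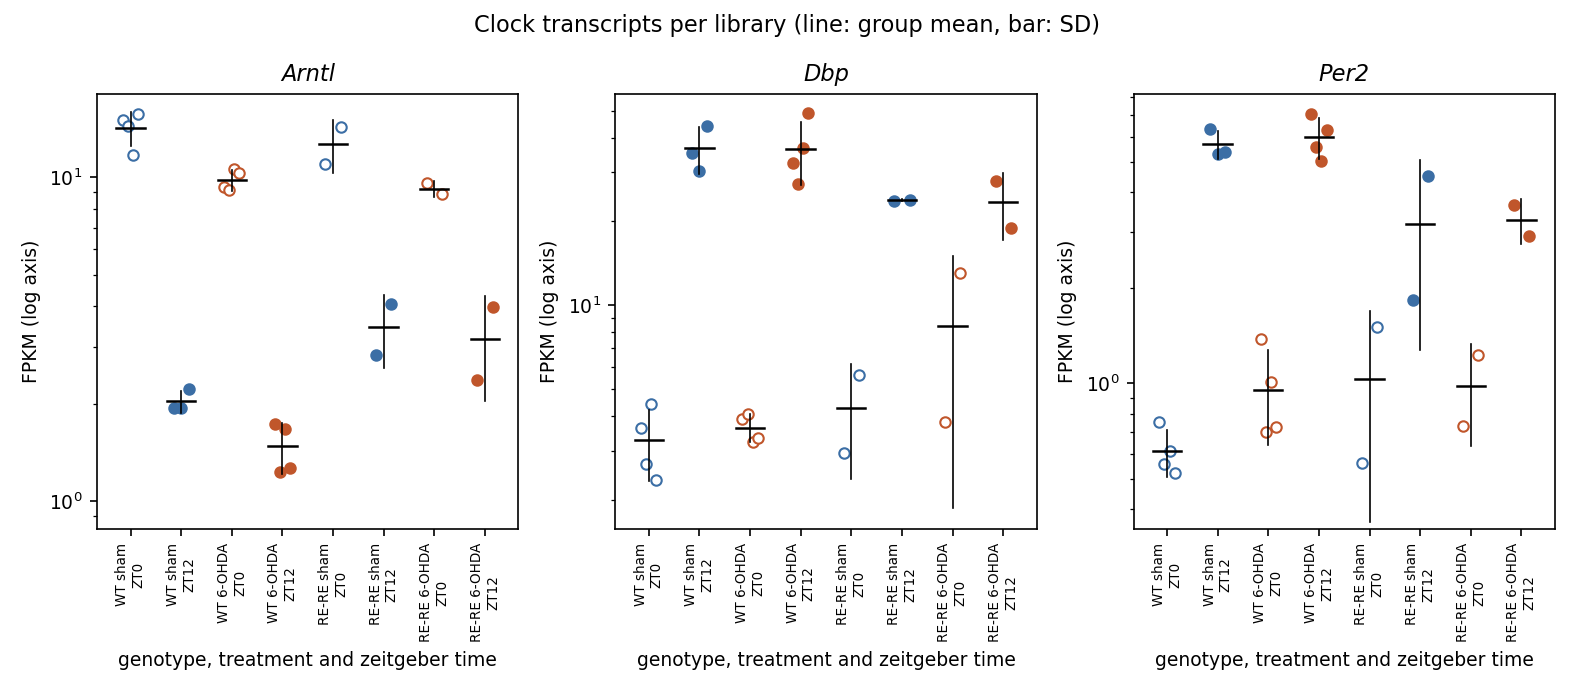
FPKM of Arntl, Dbp and Per2 in each library on log axes, by genotype, treatment and ZT, with open points for ZT0, filled points for ZT12, blue for sham and orange for 6-OHDA, a line at the group mean and a bar of 1 SD. Arntl at ZT12 lies at 1.94 to 2.22 FPKM in wild-type sham muscle and at 1.23 to 1.73 in 6-OHDA muscle, below all wild-type ZT0 libraries.

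The RE-RE mice ask which of these time differences are present when Bmal1 is restored in the Cre-expressing cells. The median residual SD of genes was 0.451 in RE-RE and 0.216 in wild-type groups, so errors and p from the pooled spread are too small for RE-RE. Arntl fell 3.69-fold in RE-RE sham muscle, from 12.7 ± 2.34 FPKM at ZT0 to 3.45 ± 0.879 at ZT12 (SD, n = 2 each; log2 -1.88 ± 0.24 SE, limma adjusted p = 0.00106). It fell 3.01-fold in RE-RE 6-OHDA muscle, from 9.24 ± 0.528 to 3.17 ± 1.13 FPKM (log2 -1.59 ± 0.24 SE, limma adjusted p = 0.0119). Dbp rose 5.87-fold in RE-RE sham muscle, from 4.27 ± 1.89 to 23.9 ± 0.163 FPKM, and Ciart, a repressor of the clock, 5.17-fold (log2 1.25 and not passing with log2(FPKM + 1)). Slc16a9, a carrier of the monocarboxylate family, and Dyrk2, a kinase, fell 3.68-fold and 2.65-fold. Each of these was higher or lower in 2 of 2 ZT12 libraries than in either ZT0 library. In RE-RE 6-OHDA muscle Slc25a34, a mitochondrial carrier, fell 5.17-fold, and Hipk2, a kinase, Pm20d2 and Slc8a1, the sodium-calcium exchanger, fell with log2 differences of -1.96, -2.12 and -1.97. Dbp (1.71 ± 0.43, adjusted p = 0.119) and Per2 (1.77, adjusted p = 0.106) did not pass there.

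In RE-RE sham muscle 1 of 6 positive-limb genes fell (4 adjusted over the list alone), and that list held its camera call with an estimated correlation (adjusted p = 0.000847). Of 12 E-box and D-box targets, 2 rose (6 adjusted over the list alone; median 0.83, adjusted p = 0.15 with an estimated correlation). The other lists called with the preset correlation had no member past the test. Their medians were -0.30 for immediate early genes (adjusted p = 0.218 with an estimated correlation), 0.42 for denervation and 0.84 for slow-fibre genes (0.768), -0.74 for extracellular matrix (0.924; 0.76 and called the other way without RE-RE sham libraries 1 and 3, preset adjusted p = 0.00677), -0.37 for fatty acid use (0.506) and 0.37 for glucocorticoid-induced genes (0.347). In RE-RE 6-OHDA muscle camera called 16 lists with the preset correlation and 0 with an estimated one. The positive limb had 1 gene past the test (2 adjusted over the list alone) and E-box and D-box targets 0 (4 adjusted over the list alone; adjusted p = 0.307 and 0.553 with an estimated correlation). Fatty acid use genes had a median of -0.94, with 0 of 18 past the test and 13 lower adjusted over the list alone (adjusted p = 0.271 with an estimated correlation). Macrophage genes had a median of 1.17 there (adjusted p = 0.553 with an estimated correlation), which became -0.60 without RE-RE sham libraries 1 and 3 and 6-OHDA library 2.

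In RE-RE sham muscle 7 genes passed, 4 higher and 3 lower at ZT12, or 5 and 2 with own totals. In RE-RE 6-OHDA muscle 14 passed, 1 higher and 13 lower, or 1 and 2 with own totals, which shifted the median of all genes to 0.20. Leaving out RE-RE sham library 1, 2 or 4 gave 14, 65 or 53 in sham muscle. Arntl passed there without any 1 library, whereas Dbp and Ciart no longer passed without library 1 (log2 2.09 and 2.23) or 3 (2.56 and 2.45), Slc16a9 without library 3 (-1.66) and Dyrk2 without library 2, 3 or 4 (-1.11, -1.44 and -1.38). Leaving out RE-RE 6-OHDA library 1, 2, 3 or 4 gave 1811, 6, 9 or 4 in injected muscle, and Arntl there no longer passed without library 2 (log2 -1.65) or library 3 (-1.22), nor did Slc25a34, Hipk2, Pm20d2 and Slc8a1 without library 2 (-1.90, -1.80, -1.95 and -1.83). With array weights limma called 0 genes in either comparison (41 and 658 at an unadjusted p under 0.05), and a fit of the compared samples alone called 21 and 0. The tests of the difference in time effect called 2 genes for 6-OHDA in RE-RE muscle (449 at an unadjusted p under 0.05) and 2 for RE-RE against wild-type sham muscle (370), small RNAs in each case, Mir1968, Gm25894 and Gm23823. Arntl's time difference changed by 0.29 ± 0.34 (SE) with 6-OHDA in RE-RE muscle (adjusted p = 0.962). Its estimated fall was smaller in RE-RE than in wild-type sham muscle, by 0.91 ± 0.30 log2 units (adjusted p = 1, or 0.0565 over the clock lists alone). The fall of Npas2 was smaller by 2.74 ± 0.65, at log2 -0.67 in RE-RE against -3.41 in wild-type sham muscle (adjusted p = 0.502, or 0.00888 over the clock lists alone). Camera called 14 and 7 lists in these tests with the preset correlation and 0 with an estimated one. For 6-OHDA in RE-RE muscle the medians include -0.61 for E-box and D-box targets and 1.39 for Schwann-cell genes (adjusted p = 0.495 and 0.298 with an estimated correlation), and the former became 0.47 without RE-RE sham libraries 1 and 3 and 6-OHDA library 2. For RE-RE against wild-type they include -0.76 for fatty acid use and 0.31 for the positive limb (adjusted p = 0.139 and 0.0704 with an estimated correlation). The count for 6-OHDA ranged from 1 without RE-RE sham library 1 to 41 without RE-RE 6-OHDA library 1, and 7 of 8 libraries moved it by over 1.5 times when left out. That for genotype ranged from 1 to 28, the latter without RE-RE sham library 2, and 9 of 11 libraries moved it as far.

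The clock score was higher at ZT12 by 0.958 ± 0.217 (SE) in RE-RE sham muscle and by 0.512 ± 0.217 in RE-RE 6-OHDA muscle. From the spread of the own groups these SE were 0.320 and 0.424, so the pooled SE and the intervals here are too narrow. The exact two-sided permutation p was 0.333 and 0.667, where 2 libraries against 2 allow none below 0.333. In RE-RE 6-OHDA muscle the times overlapped, with ZT0 library 2 at 1.04 and ZT12 library 4 at 0.997. The effect there was 0.905 without RE-RE 6-OHDA library 2 and 0.119 without library 1. The effect in RE-RE sham muscle differed from that in wild-type sham muscle by -0.537 (95% confidence interval -1.12 to 0.0443; exact two-sided permutation p = 0.193, adjusted 0.387), or by -0.842 and -0.232 without RE-RE sham library 1 and 2. In 6-OHDA muscle the genotypes differed by -1.04 (interval -1.60 to -0.47; exact two-sided permutation p = 0.0222, adjusted 0.0889), or by -0.643 without RE-RE 6-OHDA library 2. Within RE-RE mice, the effect in 6-OHDA muscle differed from that in sham muscle by -0.446 (interval -1.10 to 0.208; exact two-sided permutation p = 0.389, adjusted 0.519). That difference was -0.0526 without RE-RE 6-OHDA library 2 and -0.839 without library 1, -0.141 and -0.751 without RE-RE sham library 1 and 2, -0.288 without RE-RE 6-OHDA library 4, and 0.156 without RE-RE sham libraries 1 and 3 and 6-OHDA library 2. Of the 83 genes past the test in wild-type sham muscle, 78 had the same sign in RE-RE sham muscle and 60 in RE-RE 6-OHDA muscle, and 5 passed in both sham comparisons: Arntl, Dbp, Ciart, Slc16a9 and Dyrk2. That count was 2 without RE-RE sham library 3 and 10 without library 2.

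Comparing 6-OHDA with sham muscle in wild-type mice over both times asks how injected and uninjected muscle differ. Cd68 (ENSMUSG00000018774, chromosome 11, 69664213 to 69666153), a lysosomal protein of macrophages, rose 6.77-fold, from 2.00 ± 0.370 FPKM in sham muscle (SD, n = 7) to 14.6 ± 6.36 in 6-OHDA muscle (SD, n = 8; log2 2.76 ± 0.42 SE, limma adjusted p = 0.00112). Myh3 (ENSMUSG00000020908, chromosome 11, 67078300 to 67102291), the embryonic myosin heavy chain of regenerating fibres, rose 8.51-fold, from 1.73 ± 0.533 to 19.97 ± 18.1 FPKM (adjusted p = 0.00144). Col3a1, a fibrillar collagen, rose 5.66-fold, from 46.6 ± 18.8 to 272 ± 134 FPKM. Each of the 3 was higher in 8 of 8 injected libraries than in any sham library.

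Of 15 macrophage genes, 14 rose (15 adjusted over the list alone), with a median log2 difference of 2.20, and all 15 of 15 matrix genes rose (15 adjusted over the list alone; median 1.84). Lyz2, a lysozyme, rose 8.29-fold and Fn1, fibronectin, 5.94-fold. Of 11 regeneration genes, 8 rose (8 adjusted over the list alone; median 1.75), among them Myog, a myogenic transcription factor, at 1.80 ± 0.33 SE. Of 14 genes induced by denervation, 10 rose (10 adjusted over the list alone; median 1.18), including Runx1 (1.64), Ankrd1 (1.40) and Musk (1.19 ± 0.20 SE), the kinase that organises the neuromuscular junction. Of 10 slow-fibre genes, 8 rose (8 adjusted over the list alone; median 1.54). Myh7 (ENSMUSG00000053093, chromosome 14, 54970684 to 54994626), the slow myosin heavy chain, rose 6.87-fold, from 2.59 ± 2.48 to 11.0 ± 3.86 FPKM, and Atp2a2, the slow-fibre calcium pump, 2.81-fold. Cell-cycle genes had 7 of 10 members higher (8 adjusted over the list alone; median 1.3), with Mki67 at 2.32, and interferon-response genes 8 of 15 (10 adjusted over the list alone; median 0.57). Each of these 7 lists was called with the preset correlation and lost the call otherwise (adjusted p = 0.373 with an estimated correlation for each). Schwann-cell genes had 4 of 9 members higher, S100b at 1.11 (4 adjusted over the list alone; adjusted p = 0.452 with an estimated correlation), and lipid-synthesis genes 6 of 14 higher and 1 lower, Scd1 at 1.69 and Me1 at -1.23 (6 and 1 adjusted over the list alone; adjusted p = 0.373 with an estimated correlation). The calls of these last lists ended with own totals.

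mt-Co3 (ENSMUSG00000064358, mitochondrial genome, 8607 to 9390), a subunit of cytochrome c oxidase encoded by mitochondrial DNA, fell 5.20-fold, from 3048 ± 1930 to 544 ± 271 FPKM, and was lower in 8 of 8 injected libraries than in any sham library. Of 13 mitochondrial-genome genes, 12 fell (12 adjusted over the list alone; median -1.18, adjusted p = 0.373 with an estimated correlation), beside the lower share of mitochondrial reads given above. Of 34 nuclear genes of oxidative phosphorylation, 14 fell (15 adjusted over the list alone; median -0.36, adjusted p = 0.47 with an estimated correlation), such as Ndufa5 at -0.76 ± 0.21 SE. Of 19 glycolysis genes, 8 fell (11 adjusted over the list alone; median -0.46, adjusted p = 0.415 with an estimated correlation), Pfkfb3 at -1.56 and Aldoa, aldolase, at -0.75 (-0.05 under quantile normalization, not passing). Under quantile normalization the calls of both of these lists ended, at medians of -0.09 and -0.03. Of 13 fast-fibre genes, 6 fell and 2 rose (7 and 2 adjusted over the list alone; median -0.44, or 0.11 under quantile normalization; adjusted p = 0.373 with an estimated correlation). Actn3, the actinin of fast fibres, fell 2.04-fold (log2 -1.03, or -0.31 and not passing under quantile normalization), and Myh2, the myosin of fast oxidative fibres, rose 2.17-fold. Of 5 erythroid genes, 3 fell (4 adjusted over the list alone; median -0.65, adjusted p = 0.429 with an estimated correlation), with Hbb-bt at -0.96. Arntl fell 1.41-fold over both times on the deposited scale, with a log2 difference of -0.50 ± 0.12 (SE). Own totals of recovered reads raise injected over sham libraries, as given below, so the falls in this paragraph are smaller on that scale.

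The largest rises include Clec4d, a lectin receptor of myeloid cells (29.5-fold), and Sfrp2, a secreted modulator of Wnt signals (19.8-fold, from 0.288 to 5.96 FPKM), and the falls include Ces1d, a carboxylesterase (5.14-fold, from 12.6 to 3.63 FPKM). In all, 4469 of 12855 genes passed in limma, 2422 higher and 2047 lower, and the count stayed between 3337 and 4756 when any 1 library was left out. With each library's own total of recovered reads the split was 5121 higher and 467 lower, and the median of all genes moved from -0.04 to 0.29. None of the 23 libraries is of a vehicle-injected muscle.

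**Figure D2:**
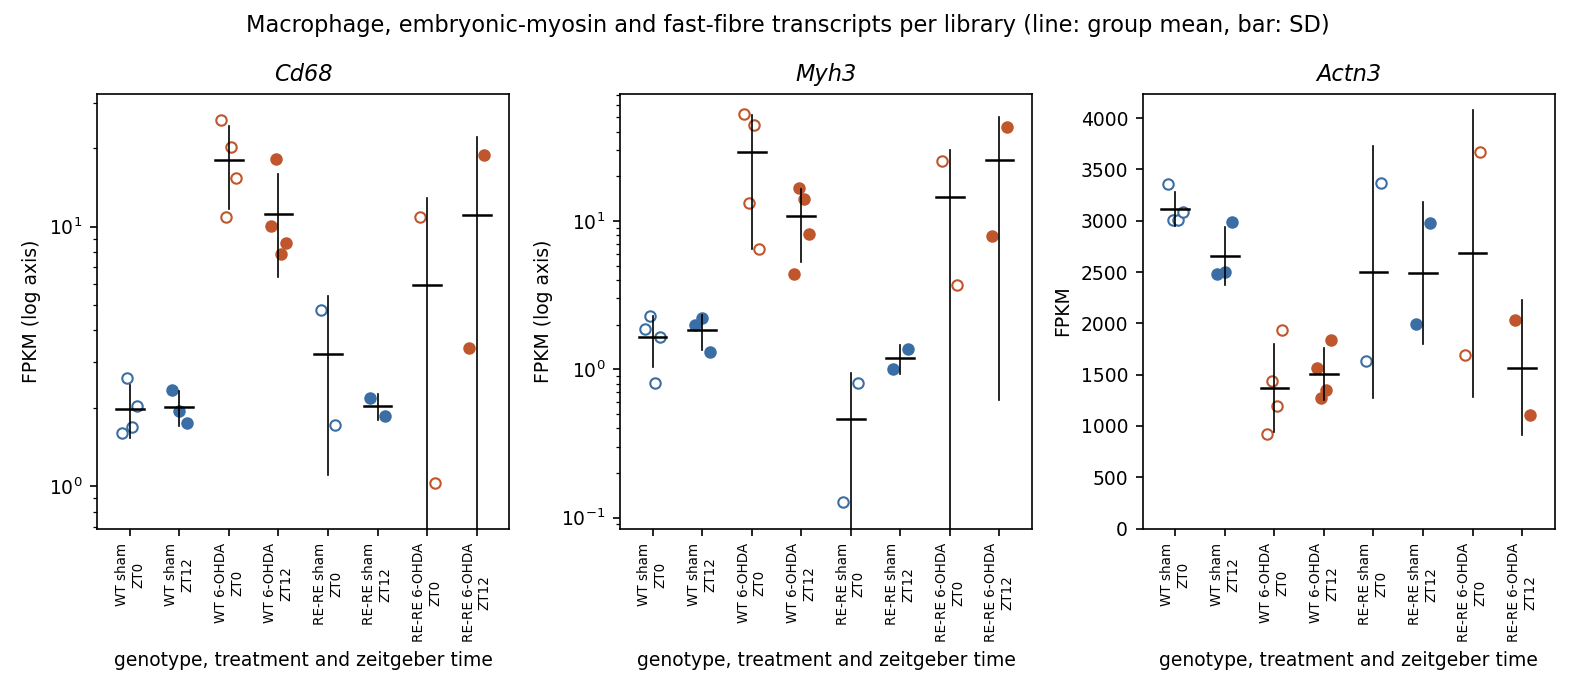
FPKM of Cd68 and Myh3 on log axes and of Actn3 on a linear axis in each library, by genotype, treatment and ZT, with open points for ZT0, filled points for ZT12, blue for sham and orange for 6-OHDA, a line at the mean and a bar of 1 SD, which runs to the bottom of a log axis where it would reach 0. In wild-type mice Cd68 lies at 7.83 to 25.6 FPKM in 6-OHDA muscle and at 1.61 to 2.62 in sham muscle.

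The treatment was compared in the same way in RE-RE mice. Myh7 rose 78.2-fold, from 0.610 ± 0.535 FPKM in RE-RE sham muscle (SD, n = 4) to 33.8 ± 25.7 in RE-RE 6-OHDA muscle (SD, n = 4; log2 6.29 ± 0.91 SE, limma adjusted p = 0.00212). RE-RE sham muscle ranged from 0.0243 to 1.32 FPKM, so the size of this fold, from means of log2 values, depends on the pseudocount. Myh3 rose 21.4-fold, from 0.825 ± 0.522 to 20.1 ± 18.1 FPKM (adjusted p = 0.00571), and Atp2a2 4.96-fold, from 6.21 ± 1.09 to 33.3 ± 14.0 FPKM. All 3 were higher in 4 of 4 injected libraries than in any RE-RE sham library. Mymk, a membrane protein for the fusion of myoblasts, rose from 0.0506 ± 0.0633 to 5.96 ± 5.97 FPKM. In RE-RE 6-OHDA library 2 it stood at 0.0919 FPKM, within the 0 to 0.143 of RE-RE sham muscle. The bone genes Ibsp (ENSMUSG00000029306, chromosome 5, 104299171 to 104311469) and Bglap fell, Ibsp from 46.5 ± 55.1 to 0.611 ± 0.746 FPKM, with 124, 12.2, 2.43 and 47.5 FPKM in RE-RE sham libraries 1, 2, 3 and 4 and at most 8.35 in wild-type sham muscle.

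Of 10 slow-fibre genes, 7 rose (9 adjusted over the list alone; median 2.5), and of 11 regeneration genes 7 rose (7 adjusted over the list alone; median 1.47). Denervation genes had 10 of 14 members higher (11 adjusted over the list alone; median 1.24), with Ankrd1 at 2.01, cell-cycle genes 7 of 10 (8 adjusted over the list alone; median 1.51) with Mki67 at 2.79, and interferon-response genes 8 of 15 (8 adjusted over the list alone; median 0.77) with Oas1a at 2.03. These 5 lists lost their call otherwise (adjusted p = 0.413 with an estimated correlation for each). RE-RE 6-OHDA library 2 stood apart in these groups: on an index over the 4469 genes called in wild-type mice, set at 0 for wild-type sham and 1 for wild-type 6-OHDA muscle, it lay at -0.226, within the range of RE-RE sham muscle, and the other 3 lay at 0.486 to 1.27. Macrophage genes had a median of 0.94 and matrix genes of 0.64, with 0 of 15 past the test in either list, and neither list was called. Without this library and RE-RE sham libraries 1 and 3, whose deviations correlate with GC content at a Spearman of -0.519 and -0.441 across genes, which are not independent replicates, a removal chosen after the data were seen, the medians were 2.39 and 1.26 (adjusted p = 0.363 and 0.563 with an estimated correlation). The index that picked out library 2 rests on genes that include 14 of 15 macrophage and 15 of 15 matrix genes, so its removal raises both medians in part by construction, and without RE-RE sham libraries 1 and 3 alone they were 1.53 and 0.58 (adjusted p = 0.768 and 0.852 with an estimated correlation). Mean log2 FPKM of the matrix list was 5.22, 3.58, 2.83 and 4.42 in RE-RE sham libraries 1, 2, 3 and 4. Wild-type sham muscle lay at 2.49 to 3.86. The bone genes below order these RE-RE sham libraries alike, and both lists hold Col1a1 and Col1a2. The matrix median therefore does not separate a weak response from a high sham level. Of 13 mitochondrial-genome genes, 8 fell (10 adjusted over the list alone; median -1.20), mt-Co3 from 4067 to 938 FPKM, and of 34 oxidative phosphorylation genes 10 fell (13 adjusted over the list alone; median -0.56; adjusted p = 0.757 with an estimated correlation for both). The latter call ended under quantile normalization, at -0.21. The mitochondrial share of recovered reads at ZT0 was 21.5% ± 8.66 in RE-RE sham and 12.4% ± 4.40 in RE-RE 6-OHDA muscle, and at ZT12 21.4% ± 2.44 and 14.5% ± 6.64 (SD, n = 2 each).

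In all, 3438 of 12855 genes passed in limma, 1522 higher and 1916 lower. With own totals 3986 were higher and 476 lower, and the median of all genes moved to 0.37. Leaving out RE-RE sham library 1, 2, 3 or 4 gave 268, 5660, 216 or 6316, and leaving out RE-RE 6-OHDA library 1, 2 or 4 gave 33, 5476 or 28. Myh7, Mymk and Atp2a2 passed without any 1 library, and without RE-RE 6-OHDA library 1 Myh3, Ankrd1, Mki67, Oas1a, Ibsp, Bglap and mt-Co3 no longer passed (log2 3.72, 1.61, 2.09, 1.57, -6.35, -6.35 and -1.85). With age as a covariate 3 passed, in a fit of the compared samples alone 2, and with array weights 0 (2329 at an unadjusted p under 0.05), and injected RE-RE mice were older than their sham group.

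Of the genes that passed in both genotypes, 1641 went the same way, 897 higher and 744 lower, where independence would give 287 and 305, and 21 went opposite ways. Pearson's correlation of both effects was 0.578 and Spearman's 0.641, across genes, which are not independent replicates. The test of the difference between the 2 effects called 9 genes, 2 higher and 7 lower in RE-RE (1900 at an unadjusted p under 0.05). Lnpep (ENSMUSG00000023845, chromosome 17, 17521410 to 17625050), a membrane aminopeptidase, had a difference of -1.93 ± 0.35 log2 units (SE), its mean going from 6.14 FPKM in RE-RE sham muscle at ZT0 to 2.42 with 6-OHDA, against 2.08 and 3.15 in wild-type muscle, and it no longer passed without RE-RE sham library 1 or 3 (-1.68 or -1.57), among others. Lmbrd2, C1galt1, an enzyme of O-glycan synthesis, and Slc25a32, a mitochondrial folate carrier, had differences of -1.88, -1.57 and -1.22. With log2(FPKM + 1) Lnpep and Slc25a32 did not pass (-1.40 and -0.90). The other members are ENSMUSG00000091562, Gm5113 and 3 small RNAs. Cd68 differed by -1.66 ± 0.71 (adjusted p = 0.296) and Myh7 by 3.51 ± 1.12 (adjusted p = 0.205). Macrophage genes had a median difference of -1.23, matrix genes of -1.38 and slow-fibre genes of 1.31, with 0 members past the test (adjusted p = 0.997 with an estimated correlation for each). The macrophage and matrix medians became 0.30 and -0.46 without RE-RE sham libraries 1 and 3 and 6-OHDA library 2. Without the 2 sham libraries alone they were -0.59 and -1.26. The matrix difference also carries the higher matrix level of RE-RE sham libraries 1 and 4 given above. The count ranged from 1 without wild-type sham ZT12 library 7 to 1115 without RE-RE sham library 4, 21 of 23 libraries moved it by over 1.5 times when left out, and array weights gave 0 (530 at an unadjusted p under 0.05).

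**Figure D3:**
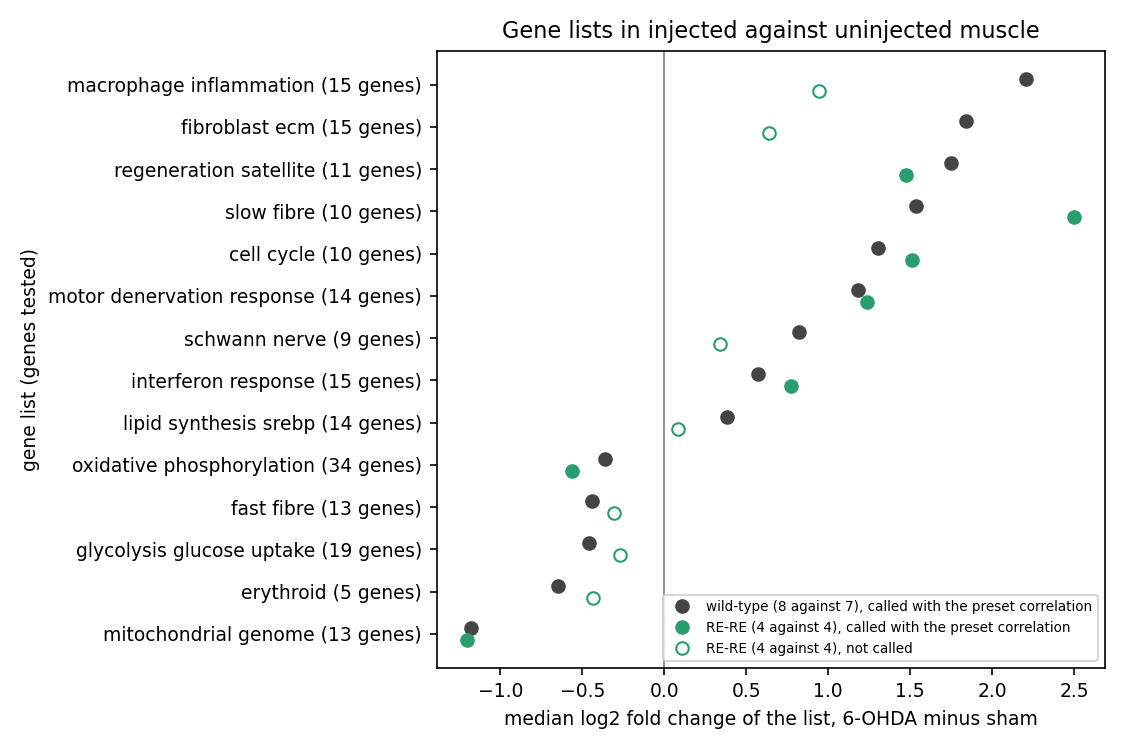
Median log2 fold change of 6-OHDA over sham muscle for each gene list called in either genotype, dark points for wild-type and green for RE-RE, filled where camera called the list with its preset correlation and open where it did not. Macrophage genes lie at 2.20 in wild-type and 0.94 in RE-RE muscle, slow-fibre genes at 1.54 and 2.5, and fast-fibre genes in wild-type muscle at -0.44, or 0.11 under quantile normalization.

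Uninjected muscle was compared between genotypes, which differ in age as well, RE-RE mice being 10 to 11 and wild-type mice 12 to 18 weeks old. Scd1 (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879), which makes monounsaturated fatty acids, was 6.19-fold higher in RE-RE muscle, at 12.7 ± 2.74 FPKM (SD, n = 4) against 2.21 ± 0.713 in wild-type (SD, n = 7; log2 2.63 ± 0.37 SE, limma adjusted p = 0.00128). Npas2 (ENSMUSG00000026077, chromosome 1, 39193731 to 39363236) was 4.29-fold higher on the mean of log2 values over both times, at 1.49 ± 0.649 against 0.637 ± 0.549 FPKM (adjusted p = 0.00239). Most of this difference lay at ZT12, at 1.27 ± 0.986 in RE-RE against 0.089 ± 0.0209 FPKM in wild-type muscle. At ZT0 Npas2 stood at 1.71 ± 0.309 against 1.05 ± 0.277 FPKM. Mymk was lower, at 0.0506 ± 0.0633 against 0.981 ± 0.478 FPKM (adjusted p = 0.00619), a call that ends with log2(FPKM + 1) (log2 -0.87). Scd1 was higher and Mymk lower in 4 of 4 RE-RE libraries than in any wild-type library. Arntl was at 12.7 ± 2.34 in RE-RE against 14.2 ± 1.74 FPKM in wild-type muscle at ZT0 and at 3.45 ± 0.879 against 2.03 ± 0.16 at ZT12 (log2 0.28 ± 0.15 SE for the mean of both times, adjusted p = 0.197).

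Of 6 positive-limb genes, 2 were higher, Npas2 and Clock (2 adjusted over the list alone; median 0.43, adjusted p = 0.398 with an estimated correlation), and the call ended under quantile normalization, at 0.34. E-box and D-box targets were not called, with 3 of 12 lower (3 adjusted over the list alone), and Nr1d1, a repressor of Arntl, at -1.42 ± 0.30 SE, or -0.63 and not passing without RE-RE sham libraries 1 and 3. Of 11 regeneration genes, 3 were lower (3 adjusted over the list alone; median -0.43, adjusted p = 0.89 with an estimated correlation): Mymk, Mymx, which acts with it in fusion, and Myh8, the perinatal myosin (-0.76 and -1.22 for these 2 with log2(FPKM + 1), not passing). Chrng, the fetal subunit of the acetylcholine receptor, was lower, at 0.0139 ± 0.0185 against 0.254 ± 0.131 FPKM, with 0 in RE-RE sham libraries 2 and 4. Its log2 difference of -3.68 depends on the pseudocount, at -0.31 and not passing with log2(FPKM + 1). Of 9 Schwann-cell genes, 3 were higher (5 adjusted over the list alone; median 0.70), among them S100b at 1.56, and of 8 adipocyte genes 2 were higher (5 adjusted over the list alone; median 2.18), with Retn, the hormone resistin, 6.63-fold higher. Of 18 fatty acid use genes, 1 was higher, Cd36, a fatty acid carrier (1 adjusted over the list alone; median 0.36, or 0.22 under quantile normalization, which ended the call). These 3 lists lost their call otherwise (adjusted p = 0.89 with an estimated correlation for each).

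The largest rises include genes of bone and of bone-resorbing cells: Bglap, osteocalcin, stood at 5.26 ± 4.75 against 0.234 ± 0.332 FPKM, Mmp9 at 10.2 ± 11.0 against 0.362 ± 0.420, and Mmp13 at 59.8 ± 71.1 against 3.32 ± 3.75. A list of bone genes added after these values were seen had mean log2 FPKM of 5.43, 3.38, 1.59 and 4.30 in RE-RE sham libraries 1, 2, 3 and 4, against -0.91 to 2.55 in wild-type sham, 0.33 to 3.09 in wild-type 6-OHDA and -0.74 to 2.11 in RE-RE 6-OHDA muscle. In all, 1278 of 12855 genes passed in limma, 611 higher and 667 lower, or 246 and 736 with own totals, which moved the median of all genes to -0.14. With age as a covariate 67 passed, Scd1 and Npas2 among them (adjusted p = 0.00531 and 0.0322), while Mymk, Chrng, Bglap, Mmp9, Nr1d1 and Clock did not (log2 -3.43, -2.66, 6.10, 5.24, -1.74 and 0.82), and a fit of the compared samples alone gave 78. Leaving out wild-type sham library 1, 2, 5, 6 or 7 gave 740, 463, 577, 730 or 291, leaving out RE-RE sham library 1, 2, 3 or 4 gave 108, 4329, 146 or 4821. Without RE-RE sham library 1, Bglap, Mmp9, Mmp13, S100b, Retn, Cd36 and Clock no longer passed (log2 4.91, 4.49, 3.46, 1.44, 2.31, 0.53 and 0.47), whereas Scd1, Npas2, Mymk and Chrng passed without any 1 library, and array weights gave 0 (1493 at an unadjusted p under 0.05).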

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

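The tests of a scaling factor, of fibre share, of a label exchange and of an uninjected muscle were chosen only after the result was seen. The bone list and the GC adjustment were also added after the bone genes had been seen to lead the comparison, with bounds set before the tested values were. The count of vehicle muscles and the other groupings of the libraries were fixed before.

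Macrophage, matrix, regeneration and denervation genes were higher in 6-OHDA than in sham muscle of wild-type mice. The tables argue against a factor between libraries, set by the authors' normalization, as the whole cause, since it would move all genes of a library alike, and the macrophage, matrix, regeneration and denervation means changed beyond the mean of all genes by 1.95 ± 0.228, 1.77 ± 0.266, 1.40 ± 0.216 and 1.06 ± 0.147 log2 units (SE). A lower share of muscle fibre RNA would raise all other cell types alike, yet macrophage genes exceeded endothelial genes by 1.74 ± 0.281 (SE), at 2.02 ± 0.235 against 0.287 ± 0.109. The injection itself could give the same pattern as loss of sympathetic nerve endings, and these cannot be told apart because 0 of the 23 libraries are of muscles injected with vehicle alone. A response to the toxin, to the needle or to the ascorbic acid solution stays open.

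RE-RE 6-OHDA library 2 lacked most of the response of the other injected muscles, with a response index of -0.226 against 0.486 to 1.27 in the other RE-RE and 0.672 to 1.52 in the wild-type injected libraries. An exchange of labels with an RE-RE sham library would need a partner with a high index, but the highest index of RE-RE sham muscle was 0.0093. A muscle that was not injected and an injected one with a partial response cannot be told apart, since the values go both ways. The index of -0.226 lies between -0.341 and 0.0093 in RE-RE sham muscle, and Cd68 at 1.03 FPKM was under the 1.61 of the lowest sham library, but Myh3 stood at 3.68 and Myh7 at 10.9 FPKM (at most 2.30 and 7.29 in any sham library), and slow-fibre genes had a mean log2 FPKM of 3.86 (at most 3.51) and regeneration genes of 1.57 (at most 1.22 in RE-RE but 1.94 to 2.82 in wild-type sham muscle). Mymk and Chrng, at 0.0919 and 0.0223 FPKM in this library, lay within RE-RE sham muscle (at most 0.143 and 0.039). No biological explanation was tested.

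Bone genes were higher in RE-RE than in wild-type sham muscle, with a median of 2.61 log2 units over 14 genes, of which 6 of the 8 seen to lead the comparison passed. Of 6 bone genes not seen beforehand 0 passed in limma, but all 6 values were above 0, from 0.27 to 2.15. The bound set beforehand, at most 2 passing, was met, but it was a poor one for genes as variable as these: Ibsp, seen to lead, did not pass at 4.92 ± 1.55 (SE) either, and Sp7 and Omd missed the threshold at 2.15 ± 0.816 and 1.28 ± 0.498 (adjusted p = 0.0873 and 0.0924). Bone carried over at dissection may explain the pattern and stays open, as does genotype or age, and Ibsp reached 6.05, 5.51 and 8.35 FPKM in wild-type sham libraries 1, 5 and 6. A GC trend of the libraries is argued against as the whole cause, since the median after a GC adjustment was 2.59 (median SE 0.765).

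In 102 groups of values, 6 values from 4 libraries lay far from the rest of their group, where chance gives about 1 in 20, or 5.1. Of the wild-type 6-OHDA ZT0 libraries, library 1 had a mean log2 FPKM of 2.225 for interferon-response genes (others 1.07 to 1.26), of 1.23 for Schwann-cell genes (0.51 to 0.63) and of 3.64 for autophagy genes (3.83 to 3.86). In wild-type sham muscle at ZT0, library 4 had 4.04 for glucocorticoid-induced genes (others 3.41 to 3.52), library 3 had -1.28 for cell-cycle genes (-0.94 to -0.87) and library 2 had 3.915 for autophagy genes (both bounds 4.02).

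Effects that differed between groups by the test of the difference include small RNAs of 68 to 157 nucleotides that are listed at 0 in some groups, so their fitted values depend on the pseudocount. The effect of 6-OHDA on the time difference was -12.32 log2 units for Gm23823 in wild-type mice, and -7.95 for Mir1968 and 9.03 for Gm25894 in RE-RE mice. The latter 2 were -1.82 and 2.56 with log2(FPKM + 1), neither passing. The time difference in sham muscle differed between genotypes by -9.40 for Gm23823 and 8.78 for Mir1968 (2.58 for Mir1968 with log2(FPKM + 1), not passing). The effect of 6-OHDA differed between genotypes by 5.55 for Mir1968 (2.05 with log2(FPKM + 1), not passing), by 3.97 for Gm27535 and by -3.65 for Gm25894. It differed by -1.88 for Lmbrd2, -1.22 for Slc25a32, -2.76 for ENSMUSG00000091562, -1.93 for Lnpep, -1.57 for C1galt1 and -1.04 for Gm5113.

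Other groupings of the same libraries were counted for each comparison. In the time comparisons of wild-type muscle the real grouping alone (1 of 35) gave as many genes as 83 in sham and as 86 in 6-OHDA muscle, with at most 0 in any other. This share, 0.0286, is the smallest that 35 groupings allow, so it argues against chance without excluding it. For 6-OHDA in wild-type mice the real grouping alone gave as many as 4469 genes (1 of 100 groupings, at most 1 in any other). That argues against chance as well, at the smallest share of 100 groupings, 0.01. The single gene for the change of the time effect was matched in 3 of 100 groupings, the real one included (at most 1 gene in any other). These groupings exchanged the times within each treatment, which also removes the time effect that both treatments share. They therefore do not test its change alone, and no conclusion is drawn from them. For RE-RE against wild-type sham muscle 4 of 100 gave as many as 1278, and 1 gave 3366, with RE-RE sham libraries 2 and 4 exchanged with wild-type sham libraries 3 and 6, which points to a structure of the samples besides the genotype. For the genotype difference in the effect of 6-OHDA 1 of 100 gave as many as 9 (at most 2 in any other). Here the genotypes were exchanged within each treatment and time, which also removes the genotype difference that both treatments share. The share therefore does not test the change in the 6-OHDA effect alone, and no conclusion is drawn from it. For 6-OHDA in RE-RE mice 2 of 18 gave as many as 3438 (at most 4769 in any other, with RE-RE sham library 2 and RE-RE 6-OHDA library 2 exchanged), too few groupings for a share under 0.05.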

How the results depend on the processing

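Voom on recovered reads, own totals, GC adjustment, the regeneration covariate and the removal of RE-RE libraries were chosen only after seeing the data. Of 271 results of named genes that passed, a gene counting once per comparison, 88 passed in the same direction under every alternative run for them, each left-out library included; not all alternatives apply to each gene and comparison. Of 14353 values of named genes under the alternatives, 12130 were the same call, 1352 no longer passed, 194 newly passed, 676 moved and 1 reversed; of the list values 1717 were the same, 183 lost and 70 gained a call, 14 moved and 17 reversed. Array weights ranged from 0.25 to 0.679 for RE-RE and from 0.735 to 4.83 for wild-type libraries. The RE-RE groups hold 2 libraries each, and a lone library left in a group is assumed to vary like the others. The recovered depth limits values near the floor, where 261 to 520 genes per library stand. The replicate numbers were not treated as pairs, and the labels name none: across genes, which are not independent replicates, 11 possible pairs correlated at -0.119 to 0.163, and 1 pair had equal age. The 4 over 0.1 and best with the own number are the RE-RE pairs (0.103 at ZT0 and 0.163 at ZT12), where 2 libraries per group mirror each other, so that both pairs of a time share a value; the highest in wild-type mice was 0.0645. The cause of each change below was not tested, except that fewer samples or genes were used where the setting says so.

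With array weights the count of genes was 698 for time in wild-type sham, 1595 for time in wild-type 6-OHDA, 27 for their difference, 7617 for 6-OHDA in wild-type, and in limma 0 for each RE-RE comparison (unadjusted counts 41 for time in sham, 658 for time in 6-OHDA, 26 for their difference, 2329 for 6-OHDA, 1493 for genotype, 43 and 530 for the genotype differences in time and 6-OHDA effects); shared time genes were 293 in wild-type and 0 for the other pairs. With GC adjustment it was 133 for time in wild-type sham, 13 in RE-RE sham, 76 in RE-RE 6-OHDA, 2259 for 6-OHDA in RE-RE and 14 for the genotype difference in the 6-OHDA effect, with 9 time genes shared between the genotypes' sham muscle and 5 lists called for that difference. With the age covariate it was 34 for time in wild-type 6-OHDA, 8 in RE-RE 6-OHDA, 3 for 6-OHDA in RE-RE, 67 for genotype and 2 for the genotype difference in the 6-OHDA effect, with 18 shared wild-type time genes and 9 lists for each of time in RE-RE 6-OHDA and genotype. With only the samples of the groups compared it was 134 for time in wild-type 6-OHDA, 3 for the wild-type difference, 21 and 0 for time in RE-RE sham and 6-OHDA (424 unadjusted), 0 for their difference (85 unadjusted), 2 for 6-OHDA in RE-RE and 78 for genotype.

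With a mean log2 FPKM of at least 1 limma called 0 for each difference between effects (142, 235, 201 and 1326 unadjusted) and 2 for time in RE-RE sham, with 2 and 1 time genes shared with wild-type sham and with RE-RE 6-OHDA. Limma-voom called 0 for the differences in time effect (298, 352 and 288 unadjusted), 2 and 7 for time in RE-RE sham and 6-OHDA and 2 for the genotype difference in the 6-OHDA effect, with 2 and 1 shared. The replicate block gave 2 for the wild-type difference in time effect, 0 for that in RE-RE (689 unadjusted) and 14 for the genotype difference in the 6-OHDA effect, beside 4239 and 3166 for 6-OHDA in wild-type and RE-RE. Quantile normalization gave 30 for time in RE-RE 6-OHDA, 765 for genotype and 1 for the genotype difference in the 6-OHDA effect, with 3 and 1 shared and 5 lists for time in RE-RE sham. Own totals gave 3 for time in RE-RE 6-OHDA, 1 for each RE-RE difference in time effect, 0 shared between RE-RE time comparisons and 8 lists for genotype. The regeneration covariate gave 3 for time in RE-RE 6-OHDA, log2(FPKM + 1) gave 0 for the RE-RE difference in time effect (398 unadjusted) and 4 for the genotype difference in the 6-OHDA effect, and no filter gave 4 for the latter and 1 shared between RE-RE time comparisons. Camera with an estimated correlation called 4 lists in each wild-type time comparison, 1 for time in RE-RE sham and 0 in the others.

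Without RE-RE sham libraries 1 and 3 the count was 158 for time in RE-RE 6-OHDA, 170 for 6-OHDA in RE-RE, 130 for genotype and 4 for the genotype difference in time effect, with 8 lists for the RE-RE difference in time effect, 8 for genotype and 5 for the genotype difference in the 6-OHDA effect. Without these and RE-RE 6-OHDA library 2 it was 11, 25 and 13 for time in RE-RE sham, 6-OHDA and their difference, 289 for genotype, 6 and 47 for the genotype differences in time and 6-OHDA effects and 1 shared, with 10, 6, 14, 8 and 8 lists for time in RE-RE 6-OHDA, the RE-RE difference in time effect, 6-OHDA in RE-RE, genotype and its difference in the 6-OHDA effect.

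These medians reversed. Matrix genes for time in RE-RE sham were 0.76 under either removal. Without the 3 libraries, time in RE-RE 6-OHDA was -0.11 for denervation, -0.60 for macrophage, -0.47 for matrix, -1.20 for adipocyte and 0.0497 for oxidative phosphorylation genes, and the RE-RE difference in time effect was 0.47 for E-box and D-box targets, -0.62 for macrophage, -1.23 for matrix, -1.28 for tenocyte, 0.16 for oxidative phosphorylation and 0.017 for glycolysis genes. That difference was -0.0896 for tenocyte genes without RE-RE sham libraries 1 and 3 and -0.00616 for oxidative phosphorylation under quantile normalization. The genotype difference in the 6-OHDA effect was 0.30 for macrophage genes without the 3 libraries. For 6-OHDA in wild-type, fast-fibre genes were 0.11 under quantile normalization and Eif4ebp1 was 0.0814 with own totals.

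Leaving out 1 library gave 25 to 59 genes for time in wild-type sham, 34 to 93 in wild-type 6-OHDA, 1 to 2 for their difference, 10 to 65 for time in RE-RE sham, 4 to 1811 in RE-RE 6-OHDA, 1 to 41 for their difference, 3337 to 4756 and 28 to 6316 for 6-OHDA in wild-type and RE-RE, 108 to 4821 for genotype, and 1 to 28 and 1 to 1115 for the genotype differences in time and 6-OHDA effects. Shared time genes were 14 to 34 in wild-type, 2 to 10 between the sham groups and 0 to 5 in RE-RE. The clock score's time effect was 1.44 to 1.55 in wild-type sham, 1.5 to 1.58 in wild-type 6-OHDA, 0.653 to 1.26 in RE-RE sham and 0.119 to 0.905 in RE-RE 6-OHDA muscle; its change with 6-OHDA was -0.00321 to 0.113 in wild-type and -0.839 to -0.0526 in RE-RE, and the genotypes differed by -0.842 to -0.232 in sham and -1.43 to -0.643 in 6-OHDA muscle.

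With log2(FPKM + 1) the effect was 1.10 in wild-type sham, 1.09 in wild-type 6-OHDA and 0.726 in RE-RE sham, and the genotypes differed by -0.706 in 6-OHDA muscle. Without RE-RE sham libraries 1 and 3 and 6-OHDA library 2 it was 0.905 in RE-RE 6-OHDA muscle, its change with 6-OHDA in RE-RE was 0.156, and the genotypes differed by -0.643 there.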

Other observations

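The test of a damped clock was chosen only after the result was seen, and the genes below were singled out after their values were seen where this is said.

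Single genes of lists that camera did not call passed the test in injected muscle (adipocyte, atrophy, endothelial and heat-shock lists, preset adjusted p = 0.0799, 0.988, 0.0646 and 0.429). Of 8 adipocyte genes, 4 rose with 6-OHDA in wild-type mice (6 adjusted over the list alone), among them Plin1, the coat of lipid droplets, 6.49-fold from 0.126 ± 0.0849 to 0.828 ± 0.467 FPKM (SD, n = 7 and 8), and Adipoq, adiponectin, 5.87-fold; with log2(FPKM + 1) neither passed (log2 0.66 and 1.14), and the list's median was 1.85. Hmox1, which degrades heme, rose 2.31-fold from 2.74 ± 0.598 to 6.49 ± 1.51 FPKM, while Nqo1, a quinone reductase and like Hmox1 a target of Nrf2, fell 2.59-fold from 13.2 ± 2.89 to 5.42 ± 1.96 FPKM. Of 16 atrophy genes, 2 rose and 4 fell (3 and 5 adjusted over the list alone; median 0.05), with the ubiquitin ligase Fbxo32 1.89-fold lower. In RE-RE mice 4 of 10 endothelial genes rose with 6-OHDA (5 adjusted over the list alone; median 0.59), Cldn5, a tight-junction protein, 2.31-fold from 10.7 ± 4.45 to 23.2 ± 2.79 FPKM (SD, n = 4 each), higher in 4 of 4 injected libraries than in any sham library; it no longer passed without RE-RE sham library 1 or 3 (log2 0.93 or 0.95). Of 15 heat-shock genes there, 4 rose and 6 fell (median -0.26), with the chaperones Hspd1 at 68.0 ± 17.1 against 111 ± 34.5 FPKM and Hspa8 at 247 ± 49.8 against 378 ± 92.5, neither passing without RE-RE sham library 1 or 3 (log2 -0.55 or -0.44, and -0.48 or -0.43).

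Th (ENSMUSG00000000214), tyrosine hydroxylase, the first enzyme of noradrenaline synthesis, was singled out after its values were seen. It was higher in injected wild-type muscle, at 0.599 ± 0.24 FPKM (lowest 0.308) against 0.138 ± 0.093 in sham muscle (highest 0.296), with a log2 difference of 2.18 ± 0.716 (SE, limma adjusted p = 0.0255). In RE-RE mice the difference was 4.18 ± 0.973 (limma adjusted p = 0.0149), a value that depends on the pseudocount: it was 0.807 with log2(FPKM + 1) (limma adjusted p = 0.0187). The 4 RE-RE sham libraries stood at 0, 0.018, 0.0229 and 0 FPKM and the 6-OHDA libraries at 0.584, 0, 0.554 and 2.96, with 0 in 6-OHDA library 2. Sympathetic nerve cells have their bodies outside the muscle, so the level of this transcript in muscle does not measure how many nerve endings remained.

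A hypothesis tested here is that 6-OHDA dampens the time difference of the clock genes in wild-type muscle. The change of the clock score's time effect was 0.0529, with a 95% confidence interval from -0.428 to 0.534, which excludes a loss of the size of -0.748, 50% of the effect in sham muscle, and leaves smaller changes open.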
